A study of Homo sapiens with 59 samples.

How the data were processed

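Bulk RNA-seq was analysed from 59 libraries of Jurkat cells collected at day 3, in 7 groups restricted to 25% of 1 essential amino acid and 5 control groups. Groups and replicate numbers were taken from the labels. The branched-chain control group holds 4 libraries that appear in the isoleucine, leucine and valine tables, and every other group holds 5. RNA was extracted with column kits and 1 µg of total RNA entered strand-specific Illumina libraries, per the labels' protocols.

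The authors deposited a table for each of the 7 amino acids, whose values are normalised counts, a signal that is never negative. The submitters' processing notes name FastQC 0.11.9, kallisto 0.50.1, DESeq2 1.44.0 and the build GRCh38, without giving their settings. The annotation release and the strand setting of the quantification are not given in the sources used here. The same control library carries different values in the 3 branched-chain tables, so each deposited table was scaled on its own, and every test was made within a table. A level set beside a level from another table is described as separately normalised. No column was left unmapped, and no library pair had identical values.

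The number of reads behind each library was estimated from the step between its low values, up to a multiple of 20. At most 81.5% of low values were whole multiples within 0.1, and in 4 libraries, branched-chain control 1, phenylalanine restricted 2, phenylalanine control 1 and valine restricted 2, fewer than 50% were. Whole reads were therefore not recovered, no count model was fitted, and the depths of those 4 libraries are the least certain. Normalised counts estimated by pseudoalignment can be divided among transcripts with shared sequence, so genes with near-identical copies and antisense transcripts are reported as uncertain.

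Genes with a mean of at least 10 normalised counts over the libraries of a table were tested on log2(normalised count + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided). Adjusted p-values are Benjamini-Hochberg values over the genes of a table, and a gene was called below 0.05. Tables were read with the R package data.table (version 1.17.8). Gene lists were tested with camera of limma, preset correlation 0.01, adjusted over all tests of 26 lists in 7 comparisons, and again with an estimated correlation. The lists hold 740 genes. Members were counted with adjustment over all genes and over the list alone. Differences between responses were tested for all 21 pairs of amino acids, as an interaction over 4 groups where controls were separate. Among isoleucine, leucine and valine the restricted libraries were compared after each table's control mean had been subtracted, which leaves the error of the shared controls out. For pairs with shared controls, unchanged groups were simulated 100 times from the libraries' own deviations with random signs. A second version of that simulation was added after the first values had been seen.

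The comparisons, lists, tests, alternative settings and rule for naming genes were fixed before the data were examined. Named in each comparison were the 6 largest rises and 6 largest falls among called genes whose libraries separated completely and whose higher group had a mean of at least 100 normalised counts. To these came the 3 members with the smallest adjusted p of the 5 lists with the smallest camera p, and the genes ASNS, TRIB3, CHAC1, DDIT3, SESN2, SLC7A11, HMGCS1, MKI67 and CD3E. Across comparisons the 10 most widely shared genes, 3 genes specific to each amino acid and 3 per branched-chain pair were added. Examples from any list were taken from its first 3 members by adjusted p. Some genes the rule allows are left out for length, and some are not reported here.

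The tests were tried on simulated data made from these libraries with known changes. Each gene was drawn independently, so the shares recovered and called do not cover deviations shared by many genes, like those in ribosomal protein mRNA. Genes changed 2-fold were recovered in 66.7% of cases for histidine, 63.6% for methionine, 60.9% for phenylalanine, 76.6% for tryptophan, 56.7% for isoleucine, 49.2% for leucine and 50.0% for valine, each from 64 to 67 changed genes among 15756 to 17353 tested, and no more than 0.0498% of unchanged genes were called.

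Alternatives were a pseudocount of 0.25 or 5, no filter or a mean of at least 100, factors of the trimmed mean of M values or equal totals applied on top, the replicate number as a block, and each library left out in turn. Added after seeing the data were library weights, omission of histidine control 3, methionine control 1 and phenylalanine control 1, whose median correlation with their group lay below 0.939, omission of the 4 libraries high in ribosomal protein mRNA, and omission of restricted library 2 of isoleucine, leucine and valine, which the block also leaves out for want of a control of its number. Gene positions and coding sequences came from GENCODE 29 on GRCh38. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.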

Results

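Jurkat cells, an established human T cell leukaemia line, were grown in medium in which a single essential amino acid had been lowered, and their mRNA was sequenced at day 3. The amino acids were histidine, methionine, phenylalanine, tryptophan, isoleucine, leucine and valine, each labelled as 25% in its restricted group. Each of the 7 comparisons asks which mRNAs differed between the restricted cells and their own control. The 59 libraries comprised 5 restricted libraries per amino acid, 5 control libraries each for histidine, methionine, phenylalanine and tryptophan, and 4 branched-chain control libraries that served isoleucine, leucine and valine together. Normalised counts summed to between 14.9 and 20.5 M per library. The steps between low values put the number of reads behind them at 11.9 M (histidine control 3) to 36.7 M (phenylalanine restricted 2), as estimates, because at most 81.5% of the low values in a library were whole multiples of the step within 0.1. Group values are mean normalised count ± SD over libraries. Fold changes are on the log2(normalised count + 1) scale, which understates the change of genes with low counts. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

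The thioredoxin-binding arrestin TXNIP, which restrains glucose uptake, rose in 6 of the 7 comparisons, and the list of cholesterol synthesis genes fell by camera in the same 6, though for histidine it had adjusted p = 0.0998 with an estimated correlation. The size of the response varied widely. Methionine restriction changed 8990 of 16889 tested genes (4697 higher, 4293 lower) and tryptophan restriction 8534 of 16630 (3920 higher, 4614 lower) at an adjusted p below 0.05 in limma. Histidine restriction changed 4946 of 17740 genes, valine 2096 of 16771, phenylalanine 1736 of 17021 and leucine 1277 of 16488. Under isoleucine restriction limma called 0 of 16623 genes, with 872 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0582. Changes of at least 2-fold were found for 2874 of the methionine genes, 1893 of the tryptophan genes, 869 of the histidine genes, 621 of the valine genes, 417 of the phenylalanine genes and 240 of the leucine genes. Scaling every library to the same total moved the median log2 fold change of all genes by 0.127 for methionine, 0.119 for phenylalanine, 0.245 for tryptophan and 0.114 for valine, so the shares of higher and lower genes in those comparisons are relative to the deposited scaling.

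**Figure D1:**
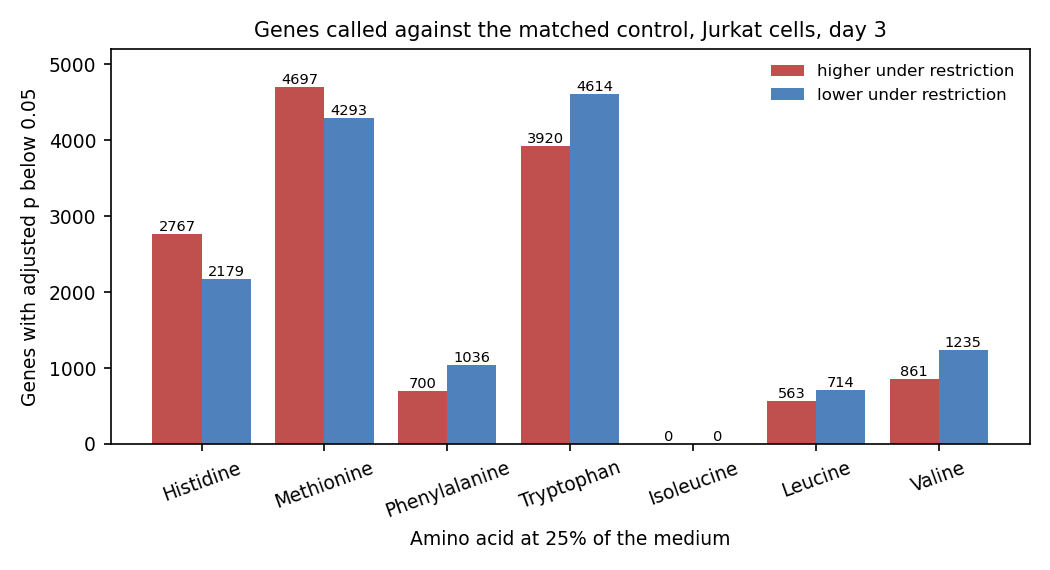
Number of genes (vertical axis) with a limma adjusted p below 0.05 that were higher (red bars) or lower (blue bars) in the restricted libraries than in the control libraries, for each amino acid (horizontal axis). The bars reach 4697 and 4293 genes for methionine and stand at 0 for isoleucine.

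Under histidine restriction TXNIP (chromosome 1, 145992435 to 145996600, GRCh38) rose 21.8-fold, to 12687 ± 939.5 against 673 ± 484 normalised counts (SD, n = 5 and 5; log2 fold change 4.45, SE 0.28, adjusted p = 1.55e-07), and its arrestin-domain relative ARRDC4 rose too (log2 fold change 2.83). SNHG12 and SNHG5, non-coding transcripts that carry small nucleolar RNAs in their introns, rose to 994 ± 80.7 against 56.1 ± 9.09 (log2 fold change 4.13, SE 0.12, adjusted p = 1.74e-10) and to 1849 ± 116 against 336 ± 68.0 normalised counts. SNHG12 (chromosome 1, 28578538 to 28583132) is annotated as antisense and is uncertain, since the strand setting of the counting is not given in the sources used here. The inducible heat-shock gene HSPA6 (chromosome 1, 161524540 to 161526910) fell to 91.0 ± 56.4 against 2611 ± 293 (log2 fold change -5.14, SE 0.42, adjusted p = 1.61e-06), and HSPA1B, which shares reads with its near-identical copy HSPA1A and is uncertain, fell to 715 ± 334 against 10874 ± 1172. In the cytosolic heat-shock list, of 18 measured members, 1 rose and 15 fell (1 and 15 adjusted over the list alone). Camera gave adjusted p = 9.44e-14, and adjusted p = 0.0867 with an estimated correlation. HSPA8 (-1.35), DNAJB1 (-2.32) and HSPH1 (-1.38), all chaperones or co-chaperones of the cytosol, were examples on the log2 scale. In the endoplasmic reticulum list, of 24 measured members, 4 rose and 10 fell (5 and 11 adjusted over the list alone), with adjusted p = 0.0467 by camera and adjusted p = 0.643 with an estimated correlation. That call was lost with factors of the trimmed mean of M values (adjusted p = 0.0625), with equal totals (0.0521) and without restricted library 2, 3 or 5 or control library 2 or 4 (0.0514 to 0.123), and the list median of -0.02 became 0.02 with either scaling.

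Genes of sterol and fatty acid synthesis fell in the same cells. In the cholesterol list, of 24 measured members, 1 rose and 23 fell (1 and 23 adjusted over the list alone). The list had adjusted p = 1.6e-23 by camera and adjusted p = 0.0998 with an estimated correlation. HMGCS1 (chromosome 5, 43289395 to 43313512), which makes the precursor of mevalonate, fell to 1249.8 ± 277 against 6442 ± 1068 normalised counts (log2 fold change -2.38, SE 0.16, adjusted p = 2.16e-07), and the later enzymes MSMO1, FDFT1 and EBP changed by -2.41, -1.49 and -1.56 on the log2 scale. In the fatty acid list, of 15 measured members, 0 rose and 12 fell (0 and 12 adjusted over the list alone). The set test, camera, gave adjusted p = 1.91e-11, and adjusted p = 0.0729 with an estimated correlation. The desaturases SCD (17495 ± 2221 against 56554 ± 6525) and FADS2 (-1.80) led it. Glycolysis and hypoxia genes, among them PDK1 (-0.96), BNIP3 (-1.17) and PGAM1 (-0.67), also fell. Of 30 measured members 0 rose and 26 fell (0 and 26 adjusted over the list alone). Its camera test gave adjusted p = 4.39e-16, and adjusted p = 0.205 with an estimated correlation. GPR183, a receptor for oxysterols, fell to 29.8 ± 8.10 against 156 ± 37.6 and differed from its response to each of the other 6 amino acids.

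The list of ATF4 targets, genes of the amino acid and stress response, rose under histidine restriction. Of 25 measured members 16 rose and 3 fell (17 and 3 adjusted over the list alone). By camera the list had adjusted p = 3.44e-06, and adjusted p = 0.167 with an estimated correlation. TRIB3, a pseudokinase of that response, rose to 6782 ± 633 against 3269 ± 373 (log2 fold change 1.06, SE 0.09, adjusted p = 2.03e-06), together with the cystine carrier SLC7A11 (1.27, adjusted p = 2.41e-06), the glutathione-degrading enzyme CHAC1 (0.90), CEBPG (0.84) and SESN2 (0.82, adjusted p = 0.00158). The mTOR inhibitor DDIT4, on the same list, fell to 2137 ± 211 against 5392 ± 878 normalised counts (log2 fold change -1.33, SE 0.10, adjusted p = 1.35e-06). The asparagine synthetase gene ASNS showed a log2 fold change of -0.01 (adjusted p = 0.916). Among tRNA synthetases MARS1 (0.87) and SARS1 (0.68) rose and the glutaminyl enzyme QARS1 fell to 2032 ± 196 against 4695 ± 263. DDIT3, the stress factor CHOP, had a log2 fold change of 0.33 (adjusted p = 0.0432) and was no longer called when restricted library 1, 2, 4 or 5 or control library 1, 2, 3 or 4 was left out (adjusted p = 0.0540 to 0.106). The T cell receptor gene CD3E (0.21, adjusted p = 0.0224) was no longer called without restricted library 1 (adjusted p = 0.0664) or 4 (adjusted p = 0.0632), and the proliferation marker MKI67 was at 0.23 (adjusted p = 0.133).

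Methionine restriction lowered the mRNAs of DNA replication and of ribosomal proteins. All 33 measured genes of the DNA replication list fell (33 adjusted over the list alone). For the list camera returned adjusted p = 9.46e-21, and adjusted p = 0.00599 with an estimated correlation. The replicative helicase subunit MCM2 dropped to 1797 ± 70.4 against 6490.0 ± 383 normalised counts (SD, n = 5 and 5), and POLD1 and CDT1 changed by -1.69 and -2.09 on the log2 scale. For the ribosomal proteins, of 78 measured members 0 rose and 77 fell (0 and 77 adjusted over the list alone). Tested as a set, the members had adjusted p = 1.55e-30, and adjusted p = 0.208 with an estimated correlation. RPL3 fell to 8861 ± 765 against 54872 ± 4419, RPL10A and RPL13A by 2.07 and 2.10, values that are uncertain because processed pseudogenes of these genes can share reads. Ribosome biogenesis genes moved the other way. Among 30 measured members 18 rose and 4 fell (18 and 4 adjusted over the list alone). Camera gave adjusted p = 0.00265, and adjusted p = 0.217 with an estimated correlation. PES1 (1.12) and PPAN (1.06) were among the rises. Mitotic genes fell. Of 30 measured members 1 rose and 28 fell (1 and 28 adjusted over the list alone). The list had adjusted p = 2.25e-12 by camera and adjusted p = 0.200 with an estimated correlation. DLGAP5 (-1.27), CCNA2 (-1.40), KIF20A (-1.10) and MKI67 (-0.71) were among the falls.

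Lipid synthesis genes fell as well. In the cholesterol list, of 24 measured members, 1 rose and 23 fell (1 and 23 adjusted over the list alone). The set test, camera, gave adjusted p = 1e-18, and adjusted p = 0.00599 with an estimated correlation. HMGCS1 fell to 685 ± 58.5 against 6829 ± 609 (log2 fold change -3.32, SE 0.08, adjusted p = 2.06e-12), and the sterol sensor INSIG1 changed by -3.05. In the fatty acid list, of 14 measured members, 1 rose and 13 fell (1 and 13 adjusted over the list alone). Its camera test gave adjusted p = 4.47e-10, and adjusted p = 0.0275 with an estimated correlation. SCD fell to 5509 ± 259.6 against 50569.5 ± 2315. Glycolysis and hypoxia genes such as ALDOC (-3.27), ENO2 (-1.84) and PDK1 (-2.22) fell as well. Among 30 measured members 0 rose and 28 fell (0 and 28 adjusted over the list alone). By camera the list had adjusted p = 3.47e-16, and adjusted p = 0.208 with an estimated correlation. In the heat-shock list, of 18 measured members, 4 rose and 12 fell (4 and 13 adjusted over the list alone). The list gave adjusted p = 0.000250 by camera and adjusted p = 0.300 with an estimated correlation, with HSPA6 at 10.2 ± 4.05 against 1463 ± 156 (log2 fold change -7.10, SE 0.23, adjusted p = 2.37e-11) and the uncertain HSPA1B at -5.06.

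TXNIP rose 26.6-fold under methionine restriction, to 13893 ± 610.1 against 522 ± 15.0 (log2 fold change 4.73, SE 0.06, adjusted p = 7.67e-16), and ARRDC4 and RGS16, a regulator of G protein signalling, rose by 4.33 and 2.44 log2 units. IL31RA, a cytokine receptor gene, rose from low counts, to 256 ± 45.5 against 9.06 ± 7.37. The stress targets divided: TRIB3 (15223 ± 1014 against 3285 ± 189; log2 fold change 2.21, SE 0.07, adjusted p = 1.27e-11) and DDIT3 (1152 ± 119 against 449.5 ± 57.2) rose, whereas ASNS (193 ± 58.7 against 853 ± 257; log2 fold change -2.15, SE 0.25, adjusted p = 5.93e-06), CHAC1 (-0.92) and SLC7A11 (-0.67) fell and SESN2 was at -0.17 (adjusted p = 0.0605). The ATF4 list as a whole was not called (adjusted p = 0.492 by camera and adjusted p = 0.780 with an estimated correlation), and of 25 measured members 11 rose and 9 fell (11 and 10 adjusted over the list alone). Serine and one-carbon genes fell. Of 20 measured members 1 rose and 15 fell (1 and 15 adjusted over the list alone). For the list camera returned adjusted p = 6.83e-07, and adjusted p = 0.207 with an estimated correlation. PHGDH, the first enzyme of serine synthesis, reached 1748 ± 169.8 against 8567 ± 985, and SHMT2 and PSAT1 changed by -1.66 and -1.15. CBS of transsulfuration fell (-1.93), and METTL16, the RNA methyltransferase that acts on the methionine adenosyltransferase mRNA, rose to 2758 ± 112 against 817 ± 122. QARS1 (-2.47) and the chitinase-like gene CHI3L2 (-3.16) fell, and CD3E was at 0.04 (adjusted p = 0.729). With every library scaled to the same total, 62.6% of the called genes were higher, against 52.2% as deposited.

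The chaperone mRNAs of the endoplasmic reticulum were lower in the phenylalanine-restricted libraries than in their controls. These controls held more HSPA5 than the histidine, methionine and tryptophan controls, in separately normalised tables. An effect of the restriction was therefore not told apart from a state of the controls. HSPA5 (chromosome 9, 125234853 to 125241330), which encodes BiP, fell 5.83-fold to 7243 ± 206 against 42264 ± 1738 normalised counts (SD, n = 5 and 5; log2 fold change -2.54, SE 0.08, adjusted p = 2.99e-09), the lumenal HSP90 gene HSP90B1 to 7208 ± 681 against 50492 ± 4439.7 (log2 fold change -2.81, SE 0.10, adjusted p = 1e-08) and the disulphide isomerase PDIA4 to 2889 ± 169 against 13802 ± 1302. In the list of the unfolded protein response of that compartment, of 24 measured members, 0 rose and 19 fell (0 and 20 adjusted over the list alone). Tested as a set, the members had adjusted p = 1.42e-31, and adjusted p = 0.000167 with an estimated correlation. Glycolysis and hypoxia genes fell alongside. Of 30 measured members 0 rose and 21 fell (0 and 25 adjusted over the list alone). Camera gave adjusted p = 1.37e-21, and adjusted p = 0.0278 with an estimated correlation. P4HA1, a collagen prolyl hydroxylase induced by hypoxia, fell to 952 ± 132 against 2863 ± 227, and BNIP3 and NDRG1 changed by -1.36 and -1.23. For cholesterol synthesis, of 24 measured members 0 rose and 18 fell (0 and 21 adjusted over the list alone). The list had adjusted p = 1.21e-16 by camera and adjusted p = 0.000738 with an estimated correlation. The sterol-responsive regulator SREBF2 (-1.48) and INSIG1 (-1.34) were examples, and HMGCS1 stood at 891 ± 57.9 against 1336 ± 139.7 (log2 fold change -0.58, SE 0.10, adjusted p = 0.00308). HSPA6 fell to 21.5 ± 12.5 against 1013 ± 95.7 (log2 fold change -5.70, SE 0.36, adjusted p = 2.12e-06), while the heat-shock list was not called (adjusted p = 0.0736 by camera and adjusted p = 0.451 with an estimated correlation).

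TXNIP rose 28.0-fold in the phenylalanine-restricted cells, to 9167 ± 496 against 352 ± 179 (log2 fold change 4.81, SE 0.23, adjusted p = 1.48e-07), followed by ARRDC4 (2.73) and the growth-inhibitory factor KLF10 (614 ± 60.9 against 163 ± 23.2). Of the 6 called genes that fell more than under every other restriction, UCP2, a mitochondrial carrier, fell to 441 ± 33.9 against 1465 ± 198. ACTG1 fell to 18624 ± 727 against 46693 ± 3516 and the purinergic receptor P2RX7 changed by -1.13. ACTG1 shares reads with near-identical copies and is uncertain. Ribosomal protein mRNAs fell. Of 78 measured members 0 rose and 32 fell (0 and 41 adjusted over the list alone). The set test, camera, gave adjusted p = 5.21e-20, and adjusted p = 0.451 with an estimated correlation. RPS26 (-1.60) and RPS4X (-1.19) were among them, and restricted library 2 and control library 1 stood 0.97 and 0.74 log2 units above the rest of their groups in these mRNAs. Mitotic genes such as TTK (-1.10), BUB1B (-0.66) and TPX2 (-0.59) fell, with adjusted p = 6.98e-08 by camera and adjusted p = 0.0998 with an estimated correlation, and of 30 measured members 0 rose and 10 fell (0 and 16 adjusted over the list alone). The ATF4 list was not called (adjusted p = 0.0818 by camera and adjusted p = 0.424 with an estimated correlation). In it DDIT4 fell (-1.65), TRIB3 stood at 18021 ± 2326 against 15178 ± 1481 (0.24, adjusted p = 0.189), DDIT3 at -0.57 (adjusted p = 0.0613), CHAC1 at 0.31 (adjusted p = 0.255) and SESN2 at 0.03 (adjusted p = 0.911). ASNS (-0.94, adjusted p = 0.0234) was no longer called without restricted library 4 (adjusted p = 0.0615) or 5 (0.0575) or control library 2 (0.0601), 3 (0.0522) or 5 (0.0563). SLC7A11 (-0.41, adjusted p = 0.259), MKI67 (-0.17, adjusted p = 0.713) and CD3E (0.19, adjusted p = 0.315) did not pass. TRIB3 was already higher in these controls than in the histidine, methionine and tryptophan controls, in separately normalised tables. Its fold change therefore does not show whether the stress response was active in both groups. The count of 1736 genes became 1128 without restricted library 1 and 1103 without restricted library 4, 4435 without the libraries high in ribosomal protein mRNA and 4868 with library weights, settings chosen after seeing the data. With every library scaled to the same total, 67.0% of called genes were higher, against 40.3% as deposited.

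Tryptophan restriction lowered DNA replication and ribosome assembly genes. All 33 measured replication genes fell (33 adjusted over the list alone). Its camera test gave adjusted p = 3.92e-22, and adjusted p = 0.00599 with an estimated correlation. MCM2 dropped to 3621 ± 196 against 10845 ± 587 normalised counts (SD, n = 5 and 5), and MCM7 and the sliding clamp PCNA changed by -1.43 and -1.50 on the log2 scale. All 30 measured ribosome biogenesis genes fell (30 adjusted over the list alone). By camera the list had adjusted p = 5.82e-19, and adjusted p = 0.00933 with an estimated correlation. BYSL (-1.60), NOB1 (-1.49) and RRP12 (-1.44) were examples. For heat-shock genes, of 16 measured members 0 rose and 15 fell (0 and 16 adjusted over the list alone). For the list camera returned adjusted p = 6.19e-11, and adjusted p = 0.0162 with an estimated correlation. The constitutive chaperone HSPA8 fell to 6840.4 ± 166 against 36603 ± 3259 (log2 fold change -2.42, SE 0.06, adjusted p = 6.8e-12), and HSP90AB1 and HSPH1 changed by -1.26 and -1.40. Mitotic genes fell too. Among 30 measured members 0 rose and 21 fell (0 and 22 adjusted over the list alone). Tested as a set, the members had adjusted p = 3.08e-06, and adjusted p = 0.464 with an estimated correlation. MKI67 changed by -0.57. Nuclear genes of oxidative phosphorylation gave adjusted p = 3.87e-08 by camera and adjusted p = 0.208 with an estimated correlation, and of 40 measured members 1 rose and 32 fell (2 and 35 adjusted over the list alone).

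ATF4 targets rose under tryptophan restriction. Of 25 measured members 21 rose and 2 fell (21 and 2 adjusted over the list alone). Camera gave adjusted p = 1.93e-10, and adjusted p = 0.0318 with an estimated correlation. TRIB3 rose 6.12-fold to 10826 ± 408 against 1768 ± 45.2 (log2 fold change 2.61, SE 0.05, adjusted p = 1.87e-13), SESN2, which restrains mTORC1, to 2389.8 ± 203 against 831 ± 65.9 and ASNS to 1049 ± 189.8 against 449.5 ± 104 (log2 fold change 1.23, SE 0.15, adjusted p = 8.85e-06). SLC7A11 (1.499), STC2 (1.47), CHAC1 (1.38), the amino acid carriers SLC6A9 (1.94) and SLC43A1 (1.41), the serine enzyme PSAT1 (1.10) and, by less, DDIT3 (0.29, adjusted p = 0.00488) rose with them. The tRNA synthetase list moved down, with adjusted p = 0.00150 by camera and adjusted p = 0.365 with an estimated correlation, and of 21 measured members 2 rose and 14 fell (2 and 15 adjusted over the list alone), including both phenylalanyl subunits FARSA (-1.70) and FARSB (-1.22). The largest rises and falls lay elsewhere. MFAP4 (chromosome 17, 19383442 to 19387240), a microfibril-associated protein of the extracellular matrix, rose 11.2-fold to 869 ± 62.7 against 77.03 ± 8.47 (log2 fold change 3.48, SE 0.10, adjusted p = 1.99e-11), KLHDC7B to 159.9 ± 27.4 against 9.27 ± 4.23 and the antisense transcript EPB41L4A-AS1, uncertain for the same reason as SNHG12, to 1229 ± 164 against 144 ± 67.6. The transcription factor genes CREB5 and JUN fell to 13.0 ± 7.40 against 686 ± 66.2 (log2 fold change -5.77, SE 0.29, adjusted p = 1.33e-09) and 156 ± 68.5 against 2239 ± 323 (log2 fold change -3.94, SE 0.24, adjusted p = 8.35e-09), and TRIB1, FXYD2 and DUSP8 changed by -3.94, -2.92 and -2.83.

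TXNIP rose 1.99-fold with tryptophan restriction, to 5838 ± 209 against 2937 ± 250.0 (log2 fold change 0.99, SE 0.06, adjusted p = 1.26e-08). In the cholesterol list, of 24 measured members, 1 rose and 20 fell (1 and 20 adjusted over the list alone). The list had adjusted p = 2.54e-06 by camera and adjusted p = 0.0399 with an estimated correlation. HMGCS1 fell to 765 ± 107 against 1311 ± 146 (log2 fold change -0.78, SE 0.10, adjusted p = 2.08e-05), and FDPS and SQLE changed by -0.93 and -0.78. INSIG1 (-0.24, adjusted p = 0.00886) and QARS1 (-0.18, adjusted p = 0.0133) were lower in the deposited values, but their log2 fold changes became 0.01 and 0.07 with every library scaled to the same total, so their direction depends on the scaling. That scaling put 70.9% of the called genes higher, against 45.9% as deposited. CD3E was at 0.06 (adjusted p = 0.383).

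Isoleucine restriction gave no gene past the threshold. TXNIP stood at 323 ± 26.3 against 306 ± 37.3 normalised counts (SD, n = 5 and 4; log2 fold change 0.08, SE 0.12, adjusted p = 0.876), HSPA5 at 51262 ± 3534 against 53069 ± 1694 (-0.05, adjusted p = 0.894) and HMGCS1 at 0.13 (adjusted p = 0.797). The stress genes TRIB3 (-0.16), ASNS (-0.06), CHAC1 (-0.11), DDIT3 (0.02), SESN2 (0.04) and SLC7A11 (0.23) and the markers MKI67 (0.10) and CD3E (-0.07) did not pass. limma called 0 genes, with 872 at an unadjusted p below 0.05, and called 1 gene when branched-chain control library 3 or 5 was left out. In data simulated from these libraries with independent genes, the same test recovered 18.5%, 56.7% and 82.8% of genes changed 1.5-fold, 2-fold and 4-fold.

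Some lists moved together in the isoleucine libraries without any member passing over all genes. Mitochondrially encoded mRNAs were higher, with a median log2 fold change of 0.22 over 13 genes and adjusted p = 2.3e-05 by camera and adjusted p = 0.464 with an estimated correlation; 1 member passed adjusted over the list alone, and MT-ND4L, a subunit of complex I, was at 0.80 (adjusted p = 0.797). The fatty acid list was higher (median 0.12, adjusted p = 0.00620 by camera and adjusted p = 0.275 with an estimated correlation), with SCD at 0.25 (adjusted p = 0.797), and 0 of 15 members passed adjusted over the list alone. Ribosomal proteins had a median of -0.24 and adjusted p = 4.79e-12 by camera and adjusted p = 0.585 with an estimated correlation, with RPS19 at 13860.3 ± 934 against 21671 ± 10285, RPL14 at -0.40 and RPL35 at -0.50 and no member past the threshold adjusted over the list alone. Branched-chain control library 1 stood 1.09 log2 units above the rest of its group in these mRNAs, and without it the ribosomal protein list turned in direction and lost its call (adjusted p = 0.620). The oxidative phosphorylation list (adjusted p = 3.06e-05 by camera and adjusted p = 0.642 with an estimated correlation) did the same (adjusted p = 0.519 without that library).

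Under leucine restriction the chaperone mRNAs of the endoplasmic reticulum were lower than in the branched-chain controls, in which HSPA5 was high as in the phenylalanine controls. A state of the controls was not told apart from an effect of the restriction. HSPA5 fell 11.8-fold to 4297 ± 356 against 50550.2 ± 1756 normalised counts (SD, n = 5 and 4; log2 fold change -3.56, SE 0.09, adjusted p = 1.76e-10), and HSP90B1 fell to 6821 ± 208 against 51336 ± 2547 (log2 fold change -2.91, SE 0.09, adjusted p = 5.64e-10). The unfolded protein response list fell. Of 24 measured members 0 rose and 21 fell (0 and 22 adjusted over the list alone). The set test, camera, gave adjusted p = 3.14e-41, and adjusted p = 0.000738 with an estimated correlation. SDF2L1 (-3.43), MANF (-3.04), CRELD2 (-2.89), PDIA4 (-2.69) and HYOU1 (-2.26), resident proteins of the same compartment, were among its members or the strongest falls. DDIT3 fell with them (log2 fold change -1.53, SE 0.21, adjusted p = 0.00140). CDH15, a cadherin gene, dropped to 1.90 ± 1.33 against 124 ± 55.6. Cholesterol synthesis genes fell. Of 24 measured members 0 rose and 20 fell (0 and 21 adjusted over the list alone). Its camera test gave adjusted p = 4.85e-19, and adjusted p = 0.0131 with an estimated correlation. HMGCS1 reached 809 ± 70.3 against 1574 ± 135 (log2 fold change -0.96, SE 0.10, adjusted p = 0.000207), and LSS and SREBF2 changed by -1.06 and -0.91.

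TXNIP rose 18.2-fold under leucine restriction, to 5319 ± 313 against 293 ± 36.8 (log2 fold change 4.18, SE 0.10, adjusted p = 1.76e-10), and ARRDC4 (2.02), the Notch target HES1 (2.05) and KLF10 (464 ± 43.8 against 144 ± 9.10) rose as well. Mitochondrially encoded mRNAs rose. Of 13 measured members 6 rose and 0 fell (10 and 0 adjusted over the list alone). By camera the list had adjusted p = 5.75e-08, and adjusted p = 0.357 with an estimated correlation. MT-ND2 reached 33920.1 ± 7966 against 13045 ± 1288 (log2 fold change 1.35, SE 0.16, adjusted p = 0.000505) and MT-ND1 changed by 1.20. Ribosome biogenesis genes were higher. Of 30 measured members 8 rose and 0 fell (10 and 0 adjusted over the list alone). For the list camera returned adjusted p = 7.04e-05, and adjusted p = 0.418 with an estimated correlation. MYC (5448 ± 591 against 3427 ± 463, adjusted p = 0.00526), NOLC1 (0.81) and MYBBP1A (0.60) were among the rises. Ribosomal protein mRNAs fell. Of 78 measured members 0 rose and 15 fell (0 and 28 adjusted over the list alone). Tested as a set, the members had adjusted p = 1.84e-13, and adjusted p = 0.555 with an estimated correlation. RPL7A was at -0.85, and branched-chain control library 1, high in these mRNAs, was among the controls. The ATF4 list moved down (adjusted p = 0.00274 by camera and adjusted p = 0.208 with an estimated correlation), and of 25 measured members 1 rose and 7 fell (1 and 9 adjusted over the list alone), with PCK2 at -0.92. TRIB3, at 9865 ± 1859 against 14840.0 ± 2756 (-0.59, adjusted p = 0.0332), was no longer called without restricted library 1, 3, 4 or 5 or branched-chain control library 3 or 5 (adjusted p = 0.0620 to 0.0901). ASNS (-0.39, adjusted p = 0.0605), SLC7A11 (-0.62, adjusted p = 0.0653), SESN2 (-0.33, adjusted p = 0.0732), CHAC1 (0.00), MKI67 (0.25, adjusted p = 0.350) and CD3E (-0.09) did not pass. As for phenylalanine, TRIB3 was already higher in these controls, with the same limit. The count of 1277 genes became 650, 511, 512 and 553 without restricted library 1, 3, 4 and 5, and 844 and 678 without branched-chain control library 3 and 5. It rose to 2699 with library weights, a setting chosen after seeing the data.

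Endoplasmic reticulum chaperone mRNAs were also lower under valine restriction than in the same branched-chain controls, with the same limit. HSPA5 fell 6.92-fold to 7795 ± 523 against 53874 ± 2334 normalised counts (SD, n = 5 and 4; log2 fold change -2.79, SE 0.11, adjusted p = 1.49e-08), HSP90B1 fell to 8468 ± 437 against 54667 ± 3155, and PDIA4 changed by -2.46. In the unfolded protein response list, of 24 measured members, 0 rose and 21 fell (1 and 21 adjusted over the list alone). Camera gave adjusted p = 3.6e-28, and adjusted p = 0.0162 with an estimated correlation. Glycolysis and hypoxia genes fell. Of 29 measured members 0 rose and 25 fell (0 and 27 adjusted over the list alone). The list had adjusted p = 3.48e-24 by camera and adjusted p = 0.0673 with an estimated correlation. P4HA1 reached 595 ± 107 against 2652 ± 167, and BNIP3 and NDRG1 changed by -1.997 and -1.63. In the cholesterol list, of 24 measured members, 0 rose and 16 fell (0 and 20 adjusted over the list alone). The set test, camera, gave adjusted p = 2.77e-16, and adjusted p = 0.0177 with an estimated correlation. The sterol carrier STARD4 (-1.99), SREBF2 (-1.53) and HMGCS1 (727 ± 119 against 1672 ± 139; log2 fold change -1.21, SE 0.14, adjusted p = 0.000199) were examples. HSPA6 fell to 20.1 ± 11.8 against 1619 ± 219.9 (log2 fold change -6.46, SE 0.38, adjusted p = 9.47e-07) and the uncertain HSPA1B by 4.64, and the heat-shock list moved down. Of 18 measured members 4 rose and 10 fell (4 and 11 adjusted over the list alone). Its camera test gave adjusted p = 0.00136, and adjusted p = 0.414 with an estimated correlation. SDK2, an adhesion molecule gene, changed by -4.10.

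TXNIP rose 30.4-fold with valine restriction, to 9466 ± 921 against 311 ± 39.0 (log2 fold change 4.93, SE 0.12, adjusted p = 1.79e-10), and ARRDC4 rose by 3.17 log2 units. PDLIM1, a cytoskeletal adaptor (184 ± 24.3 against 808 ± 175), and CKAP4 (-1.73) fell and NELFCD (1.19), of the negative elongation factor, rose in a way that differed from each other response. The ATF4 list moved down. Of 25 measured members 1 rose and 8 fell (2 and 12 adjusted over the list alone). By camera the list had adjusted p = 0.000617, and adjusted p = 0.208 with an estimated correlation. ASNS fell to 421 ± 133 against 777 ± 92.2 (log2 fold change -0.93, SE 0.21, adjusted p = 0.0125), DDIT4, PCK2 and STC2 changed by -1.47, -1.19 and -1.14, and TRIB3, at 20614 ± 1035 against 15831 ± 3085, did not pass (0.40, adjusted p = 0.0753). Nor did SLC7A11 (-0.90, adjusted p = 0.0590), DDIT3 (-0.69, adjusted p = 0.0795), CHAC1 (-0.27, adjusted p = 0.235), SESN2 (0.01), MKI67 (-0.40, adjusted p = 0.145) or CD3E (0.14). TRIB3 was already higher in these controls, with the same limit as for phenylalanine. Ribosomal protein mRNAs fell. Of 78 measured members 0 rose and 27 fell (0 and 46 adjusted over the list alone). For the list camera returned adjusted p = 2.49e-15, and adjusted p = 0.541 with an estimated correlation. RPS13 was at -1.20. Restricted library 2 and branched-chain control library 1 stood 0.59 and 1.12 log2 units above the rest of their groups in these mRNAs. Mitotic genes fell. Among 30 measured members 0 rose and 9 fell (0 and 18 adjusted over the list alone). Tested as a set, the members had adjusted p = 6.98e-08, and adjusted p = 0.206 with an estimated correlation. CCNA2 (-0.99), TTK (-0.91) and CDCA8 (-0.68) were among the falls. The count of 2096 genes became 1364, 1307 and 1366 without restricted library 1, 3 and 5 and 1110 without branched-chain control library 5. It became 4210 without the libraries high in ribosomal protein mRNA and 4549 with library weights, settings chosen after seeing the data. Scaled to the same total, 63.7% of called genes were higher, against 41.1% as deposited, and 54.1% were higher without the libraries high in ribosomal protein mRNA.

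**Figure D2:**
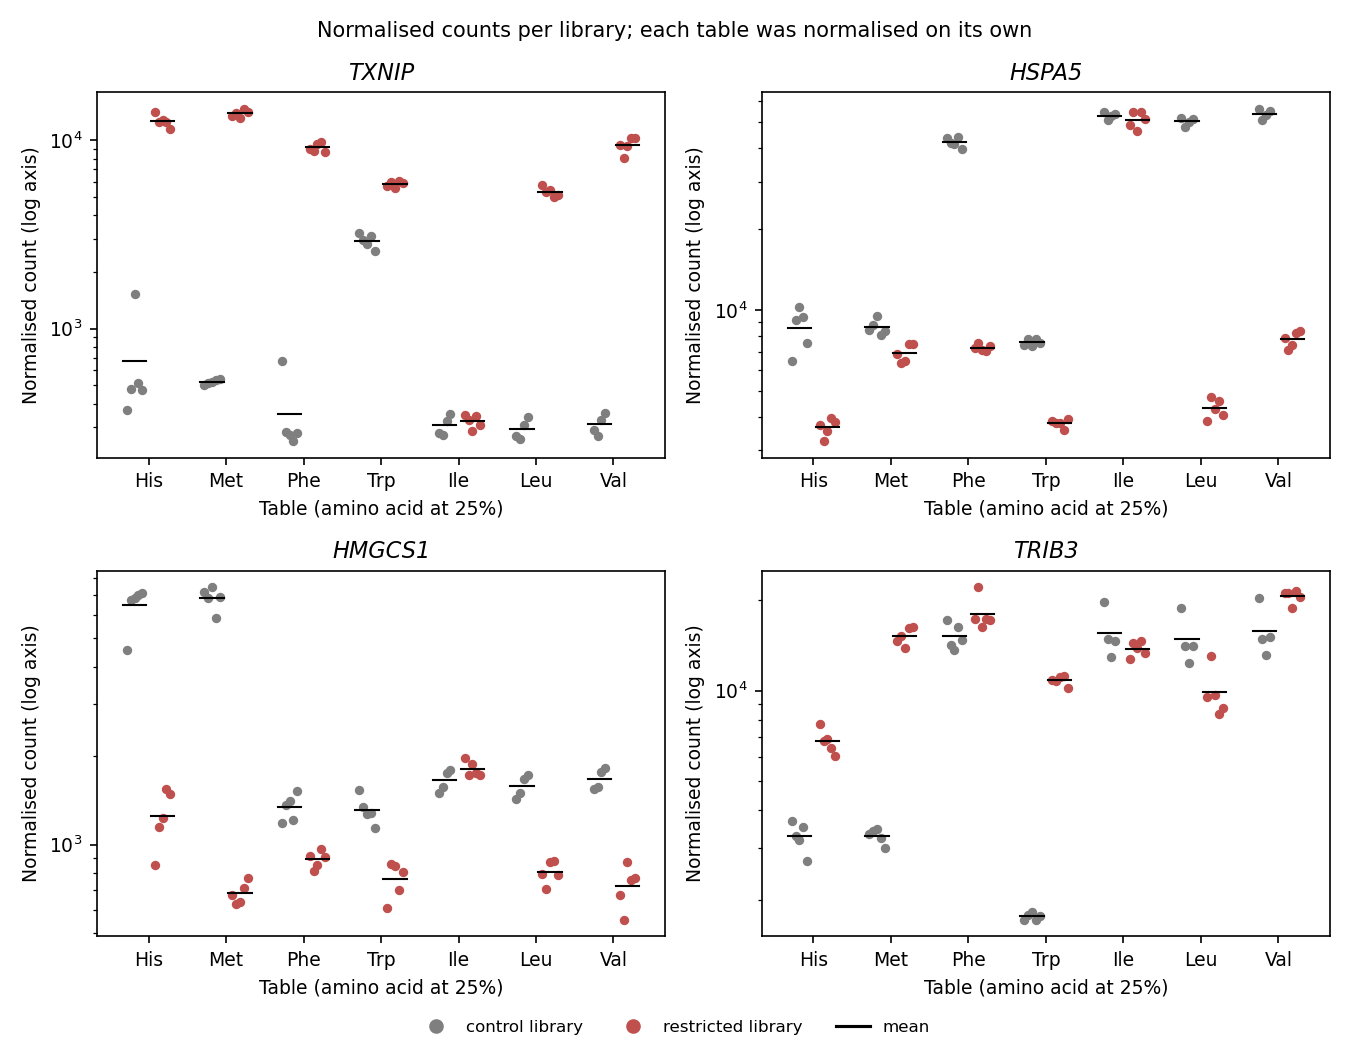
Normalised counts (vertical axes, log scale) of TXNIP, HSPA5, HMGCS1 and TRIB3 in each control library (grey points) and restricted library (red points) of the 7 separately normalised tables (horizontal axes), with black lines at group means. TXNIP means rise from 311 to 9466 in the valine table and stand at 306 and 323 in the isoleucine table.

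Across the 26 lists fixed in advance, camera called 89 of 182 tests with its preset correlation of 0.01, and 15 of these held with an estimated correlation. The 15 were cholesterol synthesis under methionine, phenylalanine, tryptophan, leucine and valine restriction, fatty acid synthesis under methionine, DNA replication under methionine and tryptophan, the endoplasmic reticulum list under phenylalanine, leucine and valine, glycolysis under phenylalanine, and the ATF4, ribosome biogenesis and heat-shock lists under tryptophan. Median, mean and test differed in sign for lists that were not called: serine and one-carbon synthesis for histidine and isoleucine, the methionine cycle for histidine, methionine and phenylalanine, interferon response for histidine, ATF4 and p53 targets for methionine, apoptosis for phenylalanine, branched-chain catabolism and autophagy for tryptophan, tRNA synthetases and heat shock for leucine, and DNA replication and the T cell receptor list for valine.

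**Figure D3:**
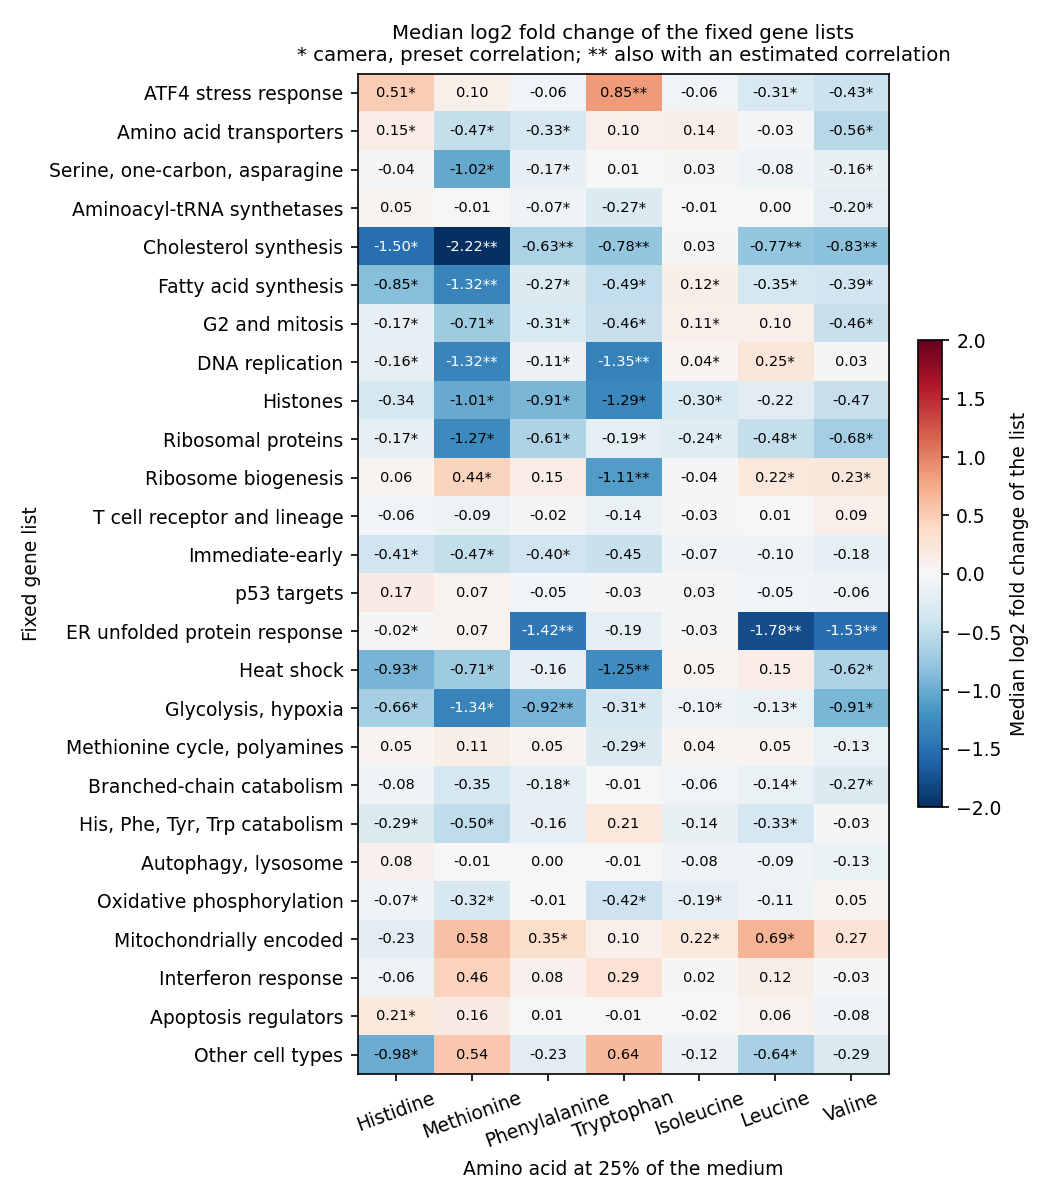
Median log2 fold change (colour and printed value) of each fixed gene list (vertical axis) in each comparison (horizontal axis), with 1 star for a camera call at an adjusted p below 0.05 and 2 stars where the call held with an estimated correlation. The endoplasmic reticulum list stands at -1.42, -1.78 and -1.53 for phenylalanine, leucine and valine, and at 0.07 for methionine.

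A few genes moved the same way under nearly all restrictions. Of 15513 genes tested in every table, 7 were higher and 56 lower in 6 comparisons, and none in 7; 49 were higher and 223 lower in at least 5, where independent calls would give 1.24 and 2.08. The counts for at least 5 were 154 and 332 without the libraries high in ribosomal protein mRNA, a setting chosen after seeing the data. TXNIP, RGS16 and SNHG12 were higher in 6, with SNHG12 at 1.18 (adjusted p = 0.00595) for phenylalanine. CHI3L2, SCD, FADS2, INSIG1, HSPA5 and QARS1 were lower in 6, although the falls of INSIG1 and QARS1 for tryptophan (log2 fold changes -0.24 and -0.18) depended on the scaling. The HSPA5 fall was -0.33 for methionine and -3.56 for leucine on the log2 scale. Because leucine and valine share control libraries, these counts are not of independent comparisons.

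Responses differed between amino acids in tests of the difference itself. Counted as specific were called genes that differed, in the direction of their change, from their response to each of the other 6 amino acids. They numbered 1863 for tryptophan, 1499 for methionine, 67 for leucine, 62 for histidine, 17 for valine and 6 for phenylalanine. Isoleucine had 0, as limma called no gene (872 at an unadjusted p below 0.05), so these counts depend on the numbers called. Without the libraries high in ribosomal protein mRNA, a setting chosen after seeing the data, the counts were 113 for histidine, 121 for leucine, 204 for valine and 57 for phenylalanine. Phenylalanine and valine differed in 113 of 16348 genes, and methionine and tryptophan in 8631 of 16094. The count for phenylalanine and valine was 190 with a mean of at least 100, 248 with equal totals, 201 without valine restricted library 2 and 1552 of 16257 without the libraries high in ribosomal protein mRNA, which both comparisons hold. Across genes, which are not independent replicates, the log2 fold changes of phenylalanine and valine correlated at r = 0.529, those of histidine and methionine at 0.375 and those of tryptophan and leucine at -0.131, or -0.203 without branched-chain control library 1. Phenylalanine and valine restriction, with separate controls, raised 232 genes and lowered 575 in common, and moved 5 in opposite directions, where independent lists would give 36.3, 77.2 and 106. Without the libraries high in ribosomal protein mRNA these counts were 858, 1116 and 108, against 284, 279 and 570.2, and the correlation was 0.460. Both control groups held more HSPA5 and TRIB3 mRNA than the histidine, methionine and tryptophan controls, in separately normalised tables. A state common to these controls may account for part of the overlap and was not tested.

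The branched-chain amino acids were compared after subtracting the shared controls. TXNIP was lower under isoleucine than under leucine or valine restriction, with differences of -4.11 (SE 0.08) and -4.85 (SE 0.09) log2 units, and HSPA5 was higher by 3.51 and 2.74. HSP90B1 differed by 2.87 (SE 0.06) from leucine and 2.64 from valine (limma adjusted p from 3.43e-13 to 1.45e-10 for the chaperones). Between leucine and valine, the mitophagy gene BNIP3 was higher under leucine by 1.98, PDLIM1 by 2.27 and DNTT, the terminal transferase of immature lymphocytes, by 1.437 (adjusted p = 1.32e-07, 1.36e-07 and 1.32e-07).

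Shared control libraries alone make such responses correlate. For leucine and valine the correlation across genes was 0.578, against a mean of 0.564 in 100 simulations of unchanged groups, and the covariance was 0.169 against a mean of 0.0853 and a range of -0.00252 to 0.305, a difference of 0.0833 from the mean. For isoleucine and leucine the correlation was 0.571 against 0.638 and the covariance 0.0996 against 0.0866, a difference of 0.0129. For isoleucine and valine the correlation was 0.416 against 0.618 and the covariance 0.0862 against 0.0900, a difference of -0.00382. When the controls were divided, 2 libraries to each comparison, the median correlations over 6 assignments were 0.218, 0.0623 and -0.00753 in the same order of pairs. Leucine and valine restriction shared 148 higher and 352 lower genes, where independent lists would give 28.9 and 54.3. Adjusted over the 16234 genes tested in both, 506 genes moved the same way, against a simulated mean of 83.8 that ranged from 0 to 3718, and divided controls gave 142 to 243 such genes and 1 to 22 that moved in opposite directions. That simulation drew each library's deviation with replacement. A version that used each deviation once, added after the first values had been seen, gave a mean of 0.05 shared genes, with a range of 0 to 2, and a mean covariance of 0.0866, at most 0.164, for this pair. The simulated counts leave out the effects and the independent lists leave out the shared controls, so the excess of shared genes over either is not assigned to a shared effect.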

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

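Tests chosen only after their result was seen are those of a common cause with TXNIP, of the spread of the shared controls, of shallow isoleucine libraries, of gene length and of deeper sequencing; the others were planned.

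The chaperones of the endoplasmic reticulum fell under phenylalanine, leucine and valine restriction, and the tables argue against a single deviating library or the scaling as the cause: the highest list median over all left-out libraries of the 3 comparisons was -1.38, and with other scalings it was -1.30. A cause that always moves TXNIP and the whole list together by a like amount is argued against by methionine restriction. There TXNIP rose by 4.73 and the list median was 0.0664 (SD over members 0.604). The methionine controls, however, held less HSPA5 than the phenylalanine and branched-chain controls. Glucose use in the latter cultures is therefore not tested by these values and stays open. HSPA5 itself was lower in all 6 comparisons with higher TXNIP (-0.33 for methionine). Mean HSPA5 stood at 42264 to 53874 in the phenylalanine and branched-chain controls and at 51262 in the isoleucine-restricted libraries, against 7577 to 8653 in the histidine, methionine and tryptophan controls, in separately normalised tables. A state of those cultures that raised HSPA5 and was absent under phenylalanine, leucine and valine restriction may account for the falls and was not tested, as a response to these amino acids themselves was not.

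No gene was called by limma for isoleucine restriction, although 872 had an unadjusted p below 0.05. The spread of the shared controls did not prevent 1277 genes from being called for leucine restriction against the same libraries. It may still hide a weaker response, as 18.5% of genes changed 1.5-fold were recovered in the simulated isoleucine data. For isoleucine 0 genes were called without the control library high in ribosomal protein mRNA. The isoleucine libraries were not shallower, with a median of 17.8 M reads against 14.5 M for leucine. Whether they are control cultures under another label cannot be told apart from a weak response, because their median correlation with the control libraries was 0.963, within the 0.940 to 0.965 among the control libraries themselves (median 0.953). A restriction too mild to act on these cells may also account for it, and was not tested.

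Ribosomal protein mRNA stood above the rest of the group in 4 libraries: by 1.09 to 1.12 log2 units over the 3 tables in branched-chain control 1, 0.97 in phenylalanine restricted 2, 0.74 in phenylalanine control 1 and 0.59 in valine restricted 2. The tables argue against length bias as the whole cause, because genes of matched length carried at most 17.0% of the deviation in any table, but a length trend was present and a part stays open: deviations correlated with gene length across genes at -0.242 to -0.159 (Spearman) in these libraries, against -0.157 or higher in the others. Deeper sequencing may play a part and cannot be told apart, as 3 of the 4 libraries had the most reads of their group and phenylalanine control 1, with an estimated 15.1 M, did not. No biological explanation was tested, since the libraries lie in 4 different groups. The same 4 libraries held the fewest low values at whole multiples of the read step, 36.4 to 49.2%.

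Other divisions of the libraries were drawn 100 times per comparison, the real one included. They ask only whether an arbitrary division of these libraries gives as many genes. A difference between cultures or batches that has nothing to do with the restriction would also single out the real division, and cannot be excluded in this way. An arbitrary division of the libraries is argued against for histidine, where only the real division, 1 of 100, gave as many as 4946 genes. The highest other gave 45. The same held for methionine (8990, highest other 1), phenylalanine (1736, highest other 1), tryptophan (8534, highest other 1), valine (2096, highest other 2) and leucine (1277, highest other 162, in the division that set leucine restricted 2 with the control libraries). For isoleucine the real count of 0 is reached by any division (100 of 100, highest other 2), so the divisions say nothing about chance there.

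A library lay far from the rest of its group in 36 of 528 gene and group combinations, where chance gives about 1 in 20; each value here is its gap to the nearest other library divided by the range of the group. Branched-chain control 1 was the highest for CRELD2 (0.940), MANF (0.873) and SDF2L1 (0.855), for RPL35 (0.896), RPL7A (0.849), RPS13 (0.870) and RPS19 (0.878), and for DDIT3 in the isoleucine, leucine and valine tables (0.961, 0.953 and 0.948). Branched-chain control 4 was the lowest for SESN2 in the same tables (0.931, 0.899 and 0.849). Histidine control 1 was the lowest for HMGCS1 (0.846) and PGAM1 (0.803), and histidine control 3 the highest for TXNIP (0.874). Phenylalanine restricted 2 was the highest for CHI3L2 (0.747), HSP90B1 (0.838), RPS26 (0.780), RPS4X (0.730), SNHG12 (0.762) and TRIB3 (0.822) and the lowest for MKI67 (0.739). Phenylalanine restricted 4 was the highest for UCP2 (0.7675). Phenylalanine control 1 was the highest for TXNIP (0.925) and HSPA6 (0.770) and the lowest for MKI67 (0.802), and phenylalanine control 4 the highest for QARS1 (0.855) and SNHG12 (0.796). Leucine restricted 2 was the highest for PCK2 (0.766) and TRIB3 (0.724). Methionine restricted 1 was the lowest for POLD1 (0.891), methionine restricted 3 the highest for MKI67 (0.722) and methionine restricted 4 the highest for PES1 (0.724). Tryptophan restricted 1 was the lowest for HSP90AB1 (0.722) and valine restricted 2 the lowest for STARD4 (0.814).

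Every pair of amino acids held genes whose responses differed in limma's test of the difference. Histidine differed from methionine in 5671 genes, from phenylalanine in 1589, from tryptophan in 7016, from isoleucine in 1984, from leucine in 2686 and from valine in 2161. Methionine differed from phenylalanine in 4791 genes, from tryptophan in 8631, from isoleucine in 6007, from leucine in 5977 and from valine in 4572. Phenylalanine differed from tryptophan in 5265 genes, from isoleucine in 893, from leucine in 756 and from valine in 113. Tryptophan differed from isoleucine in 5302 genes, from leucine in 6423 and from valine in 5675. Isoleucine differed from leucine in 2844 genes and from valine in 4647, and leucine from valine in 3633. Tests among these branched-chain amino acids leave out the error of the controls, which all other pairs carry. The branched-chain counts therefore cannot be compared with the others. Without the libraries high in ribosomal protein mRNA, left out after seeing the data, phenylalanine differed from histidine in 3178 genes, from isoleucine in 2549, from leucine in 1950 and from valine in 1552.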

How the results depend on the processing

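Library weights, the omission of libraries by their correlation or ribosomal protein mRNA and that of restricted library 2 of isoleucine, leucine and valine with no block were tests chosen after seeing the data; the others were planned. Counts of called genes stayed within 1.5 times of their reported value with either pseudocount, with a mean of at least 100, with other scalings and, except for isoleucine, without a filter. Library weights gave 4868 genes for phenylalanine, 2699 for leucine and 4549 for valine, and without the libraries high in ribosomal protein mRNA 4435 were called for phenylalanine and 4210 for valine; without a filter 1 was called for isoleucine. The cause was not tested. Leaving out each library in turn gave 3847 to 5065 genes for histidine, 8370 to 8966 for methionine, 1103 to 2542 for phenylalanine, 7900 to 8312 for tryptophan, 0 to 1 for isoleucine, 511 to 1674 for leucine and 1110 to 2657 for valine, with 1 fewer library behind each, and 86 to 93 called lists. Of the 89 called lists, 15 held with an estimated correlation, 87 with factors of the trimmed mean of M values, 84 with equal totals, 78 of 86 tested with a mean of at least 100, 89 with a pseudocount of 5 and 79 with the doubted libraries left out. Without some library 18 of the called lists and 49 named results lost their call, but not all 688 named results had one. The lists that turned in direction were ribosomal proteins (adjusted p = 0.620) and oxidative phosphorylation (0.515) for isoleucine with the doubted libraries left out. Over the left-out libraries their camera adjusted p ranged from 1.6e-17 to 0.620 and 2.3e-08 to 0.519 respectively, each highest without branched-chain control 1. Among named genes, INSIG1 (0.00554) and QARS1 (0.0668) turned from lower to higher on the log2 scale for tryptophan with equal totals, which is a matter of the scaling itself. Differences between phenylalanine and valine numbered 190 with a mean of at least 100 and 248 with equal totals. Without the libraries high in ribosomal protein mRNA differing genes numbered 1552 for this pair, 3178 for histidine and phenylalanine, 2549 for phenylalanine and isoleucine and 1950 for phenylalanine and leucine, and 154 genes were higher and 486 higher or lower in at least 5 comparisons; the cause was not tested. The planned count models were not run, because whole reads were not recovered. In data simulated with independent genes the test recovered 13.8% (valine) to 61.3% (tryptophan) of genes changed 1.5-fold. It recovered 49.2% (leucine) to 76.6% (tryptophan) of those changed 2-fold and at most 96.8% (tryptophan) of those changed 4-fold. Whether depth or the number of libraries sets these shares was not tested.

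The replicate numbers did not pair the samples. Of the same-numbered pairs 1 of 5 for histidine, 1 of 4 for isoleucine and 1 of 4 for valine had deviations correlated above 0.1, and 0 in the other tables, and no comparison had every restricted library correlating best with its own number. With the number as a block, 803 genes were called for phenylalanine, 834 for leucine and 3067 for valine, 86 of the 89 lists kept their call and 26 genes were higher in at least 5 comparisons. These fits also lack restricted library 2 of isoleucine, leucine and valine, which has no control of its number; without these libraries and with no block, a setting chosen after seeing the data, the counts were 1329 for leucine and 2595 for valine, 89 lists and 53 genes. With the block differing genes numbered 982 for histidine and phenylalanine, 1114 for histidine and isoleucine, 262 for phenylalanine and isoleucine, 189 for phenylalanine and leucine and 12 for phenylalanine and valine, against 1589, 1680, 693, 778 and 201 in the same libraries with no block. The block leaves fewer residual degrees of freedom.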

Other observations

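The tests of the amino acid content and the synthetases against other assignments of amino acids were chosen after the result was seen, as was the comparison of host gene medians with the SD of their members; the others were planned.

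The genes of this and the next paragraph were chosen after their values were seen. They are single genes, and the T cell receptor and lineage list was not called in any of the 7 comparisons. RAG1, a subunit of the recombinase that joins antigen receptor segments, fell under tryptophan restriction to 3178 ± 242 against 9056 ± 568 normalised counts (SD, n = 5 and 5; log2 fold change -1.51, SE 0.06, adjusted p = 3.59e-10), and the thymocyte surface genes CD1A and CD1B changed by -1.46 and -1.22 on the log2 scale. RAG2, the partner of RAG1, fell under methionine restriction to 190.5 ± 5.39 against 473 ± 16.0 (log2 fold change -1.31, SE 0.09, adjusted p = 3.55e-08), under phenylalanine restriction by 0.89 and under valine restriction by 1.58. The costimulatory receptor gene CD28 rose under methionine restriction to 226 ± 36.4 against 36.8 ± 10.7 (log2 fold change 2.62, SE 0.22, adjusted p = 2.47e-07). CD4 and CD1E fell under phenylalanine restriction (-2.05 and -1.05). With valine restriction HES1, a Notch target, rose to 230.4 ± 36.8 against 42.4 ± 21.4 (log2 fold change 2.52, SE 0.28, adjusted p = 0.000153), as did the adaptor LCP2 (0.90).

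EGR1 fell under histidine (-1.19), methionine (-1.74) and phenylalanine restriction (-1.32), and FOS under methionine (-2.73) and phenylalanine (-2.23). In the immediate-early list 9, 8 and 7 of 20, 20 and 19 measured members fell (9, 8 and 10 adjusted over the list alone) and 1, 1 and 0 rose. The list fell by camera in these 3 comparisons (adjusted p = 7.04e-05, 0.0138 and 0.000325), and had adjusted p = 0.264, 0.396 and 0.208 with an estimated correlation. CDKN1A, the cell cycle inhibitor p21, fell under tryptophan restriction to 48.7 ± 12.9 against 259 ± 22.2 (log2 fold change -2.43, SE 0.19, adjusted p = 1.23e-07), with the p53 targets PMAIP1 (-1.24) and AEN (-1.38), while 8 of the 20 measured members of the p53 list rose and 7 fell (8 and 8 adjusted over the list alone) and the list was not called (adjusted p = 0.834). TIGAR, a p53 target that slows glycolysis, rose under histidine (0.64) and methionine restriction (1.08). WIPI1, needed for early autophagosomes, fell under leucine (-1.71) and valine restriction (-1.77) and rose under tryptophan restriction (1.14). MAT2A, which makes S-adenosylmethionine, rose under leucine (0.75) and valine restriction (0.76). The interferon list was not called in any comparison, although 14 of 31 measured members rose and 5 fell under methionine restriction and 9 rose and 3 fell under tryptophan restriction (the same counts adjusted over the list alone). Among interferon genes IRF7 rose under histidine (1.37), ISG15 under methionine (1.23) and XAF1 under tryptophan restriction (1.02), where HERC5 fell (-1.41).

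The list of markers of other cell types was lower by camera under histidine (median -0.98, adjusted p = 0.0394; adjusted p = 0.585 with an estimated correlation) and leucine restriction (median -0.64, adjusted p = 0.0148; adjusted p = 0.207 with an estimated correlation). Of 14 and 12 measured members 3 and 1 fell, and 1 and 0 rose, with the same counts adjusted over the list alone. The histidine call was lost without restricted library 5 (adjusted p = 0.0644) or control library 3 (adjusted p = 0.157), and both were lost with a mean of at least 100 (adjusted p = 0.0859 and 0.146).

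One hypothesis was that the tRNA synthetase charging the restricted amino acid rises more than the other synthetases. Among 21 cytosolic synthetases it ranked highest under tryptophan (WARS1, log2 fold change 0.47, adjusted p = 0.000136), isoleucine (IARS1, 0.21, adjusted p = 0.797), leucine (LARS1, 0.33, adjusted p = 0.147) and valine restriction (VARS1, 0.73, adjusted p = 0.00297), but MARS1 ranked 7 for methionine (0.21, adjusted p = 0.01004) and HARS1 14 for histidine (-0.04, adjusted p = 0.667). For phenylalanine the subunits FARSB and FARSA ranked 3 and 16. The mean rank over the 7 comparisons was 4.93, against 11.0 by chance (permutation p = 0.00472, two-sided, 1e+05 resamples, with the comparisons taken as independent although the branched-chain ones share controls). Some synthetases are high in several comparisons at once, so amino acids were also reassigned to comparisons in all 5040 ways, which gave a mean rank of 9.40 and an exact one-sided p of 0.0258. The values are consistent with a response of the synthetase to its own amino acid, as a hypothesis, while only MARS1, WARS1 and VARS1 of the 8 genes passed limma's threshold on their own.

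Another hypothesis was that mRNAs of proteins rich in the restricted amino acid fall. The share of each amino acid in the encoded protein was correlated with the log2 fold change across 10433 to 10576 genes, which are not independent replicates. The restricted amino acid gave 1 of the 3 most negative of 20 Spearman correlations in 5 of 7 comparisons (exact binomial p = 0.00122). That p treats the comparisons as independent, although isoleucine, leucine and valine share control libraries and their log2 fold changes correlate at 0.416 to 0.578 across genes. It was the most negative for histidine (-0.110), methionine (-0.122), phenylalanine (-0.159) and valine (-0.162), and ranked 2 for leucine (-0.198). It ranked 13 for tryptophan (0.0311) and 19 for isoleucine (0.219), against the hypothesis. With GC content at the third codon position and coding length removed the ranks were 1, 1, 1 and 1 for the first 4, 1 for leucine, 11 for tryptophan and 18 for isoleucine. Over the 5040 assignments the mean correlation was -0.0717 for the real one and -0.0300 on average (exact one-sided p = 0.0377), p = 0.00139 exact with composition and length removed, and p = 0.0339 exact outside the fixed lists. The correlations are small, and the data may reflect a codon or protein-composition effect or a property that goes with composition and was not tested.

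A further hypothesis, raised by SNHG12, SNHG5 and EPB41L4A-AS1, was that other host genes of small nucleolar RNAs rise as well. Their median log2 fold changes over 21 or 22 measured genes were 0.0364 for histidine, 0.0392 for phenylalanine, 0.197 for tryptophan, 0.0879 for leucine, 0.0858 for valine, -0.358 for methionine and -0.151 for isoleucine. Members that passed were 7 higher and 2 lower for histidine, 3 and 8 for methionine, 7 and 3 for tryptophan, 4 and 0 for phenylalanine, 3 and 0 for leucine, 3 and 0 for valine and 0 and 0 for isoleucine. The criterion set before the result was seen counted a median at or below 0 against a shared rise, and methionine and isoleucine met it. It took no account of the spread between members, and every median lay closer to 0 than the SD of its members (0.655 to 0.967), a comparison made after the values were seen. That SD describes single genes and not the uncertainty of a median, so this comparison cannot decide whether a rise was shared. The planned criterion rests on the sign of a median without its uncertainty, so it does not exclude a shared rise for methionine and isoleucine. For the other comparisons a shared rise cannot be told apart from none. With the preset correlation camera called the host genes only for isoleucine, and lower (adjusted p = 0.0223), while the 7 comparisons had adjusted p = 0.535 to 0.700 with an estimated correlation.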
